A study of Mus musculus with 6 samples.

How the data were processed

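Messenger RNA abundance was measured by RNA sequencing in 6 libraries of the mouse line mRPMaxKO, 3 of the control group and 3 with MAX restored. Per the labels' protocols, doxycycline was given for 4 days, with no word on whether the control arm received it, RNA was extracted with TRIzol and libraries were made from 500 ng of total RNA with the NEBNext Ultra RNA kit, which does not mark strand. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.5.2a, featureCounts from Subread 1.6.0 and the genome build mm9. The deposited values are raw counts of reads per gene symbol, not normalized, 1 file per library. Per the file headers the authors counted without strand over the exons of the UCSC mm9 gene annotation, with no option set to count reads that map to several places or overlap several genes. Reads of a gene and of an overlapping or antisense partner therefore cannot be told apart, and genes with near-identical copies can lose reads. The annotation holds no mitochondrial genes and no row without a gene name, and no other column of values per sample was present. The libraries hold no known added standard, so all changes are relative to the rest of the transcriptome.

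Groups were taken from the labels. Genes were kept by edgeR 4.0.16's filterByExpr with a minimum count of 10, which left 12664 of 24391 (18279 had a count). Counts were scaled by TMM and tested with edgeR's quasi-likelihood test, group only, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the absolute coefficient over the square root of the F statistic, rather than taken from an interval as planned, since the fit gives none. CPM values are counts scaled to a library's size after TMM. The biological coefficient of variation was 4.28%. In R 4.3.3, gene lists were tested with limma 3.58.1: camera on log2 CPM (prior count 2) with a preset correlation of 0.01, then with an estimated correlation, and fry. Adjustment ran over the 23 of 27 lists with at least 3 tested members. The 27 lists were fixed before the data were examined. They cover the MYC-MAX-MXD network, metabolism, ribosomes, cell cycle, cell identity, stress, histones and other cell types. The list of mitochondrially encoded genes had no member in the annotation. Lists past the preset test numbered 10, with 9 lower and 1 higher, and 1 of the 10 also passed with an estimated correlation. With fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 19 passed.

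The genes named were also chosen by a rule set before the data were examined: Max, every network gene, the 10 largest changes in each direction, and up to 4 members of each list with the smallest p (2 where none passed). Some genes that the rule takes are not reported here. The largest changes were taken among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups. Members named because a count was 5 or fewer, and those named outside the rule in the accounts of single lists, were chosen after their values were seen. Ratios for genes with few counts have exact binomial 95% intervals, which cover counting error only because reads without molecular identifiers are not independent molecules.

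Replicates were compared by a chi-square test over genes with at least 20 counts in a pair, and no pair lay within sampling noise. Genomic stretches were found from medians of 51 neighbouring tested genes in mm9 order, over 12655 placed genes. Coordinates come from the files. The reference given was another build, GRCm38, and was used only for the GC content of transcripts, which was found for 99.4% of placed genes. The scripts were tested on simulated data made from the means, library sizes and dispersions of these libraries for the comparison of MAX restored with control (12557 genes tested). Changed genes were recovered in 55.1% of cases at 1.25-fold, 86% at 1.5-fold, 98.0% at 2-fold and 100% at 4-fold, and 13 of 12359 unchanged genes were called. Few genes were changed in that simulation, whereas 8040 of 12664 were called in the data, so these rates do not carry over directly. Alternatives covered other scalings, filters and thresholds, DESeq2 1.42.0, limma voom, the replicate number as a block, trends with gene length and GC content, thinning to 10046899 counts, and leaving out each library. No library was left out of the main results.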

Results

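RNA was sequenced from mRPMaxKO, a mouse cell line derived from a lung tumour lacking Rb1, p53 and Max, genotypes that model small cell lung cancer. A polyclonal population of the line carried a doxycycline-inducible lentiviral vector and had been selected with puromycin. The treatment protocol, worded alike for all libraries, gives 4 days of doxycycline, cells were below passage 20, and libraries were made from 500 ng of total RNA. The 6 libraries fell into 2 groups of 3, control and MAX restored, named by group and number. The labels do not say whether the control arm carried an empty vector or whether it received doxycycline, so the groups may differ in either besides MAX. They also do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The question was which transcripts change when MAX is put back into cells that lack it. Each control library held between 10046899 and 10425210 counts over 24391 annotated genes, and each MAX restored library between 10253303 and 11925909. The number of genes with a count lay between 15510 and 16147 per library. The first principal component of log2 CPM held 85.5% of the variance and separated the groups. Within groups, control 1 stood apart. Its chi-square per degree of freedom was 8.91 against control 2 and 10.2 against control 3, where the 3 MAX restored pairs lay between 1.24 and 1.46. Rn45s, the ribosomal RNA precursor, took 0.996% of the counts of control 1 (95% exact binomial interval, counting error only, 0.990 to 1.002), 0.187% of control 2 (0.184 to 0.190) and 0.109% of control 3 (0.107 to 0.111). It took between 0.121% and 0.160% of the MAX restored libraries.

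Max, the partner that MYC proteins need to bind DNA, rose 20.9-fold, from 63.5 ± 2.47 CPM in the controls to 1327 ± 18.7 CPM in the MAX restored libraries (SD, n = 3 each). Its raw counts were 639, 691 and 620 in controls 1, 2 and 3, and 15979, 14933 and 13369 in MAX restored libraries 1, 2 and 3. The log2 fold change was 4.38 (SE 0.04), with an adjusted p of 1.68e-24 in edgeR's quasi-likelihood test. The gene lies on chromosome 12 of mm9, from 78038256 to 78063235 on the minus strand, with 5 distinct exons in the annotation used. Counts summed over the gene do not show which exons the reads of the control libraries came from, nor separate vector from endogenous transcripts.

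Among the other members of the MYC-MAX-MXD network, the MYC genes rose and most of the MAX partners of the MXD and MGA type fell. Mycn rose 2.81-fold (log2 1.49, SE 0.18), from 2.61 ± 0.385 to 7.36 ± 0.851 CPM (SD, n = 3). Mycl rose 2.03-fold (log2 1.02, SE 0.09), Myc 1.27-fold (0.35, SE 0.08) and Mxd1 1.16-fold (0.21, SE 0.07). The fallers were Mxi1 at log2 -0.78 (SE 0.05), the repressor Mnt at -0.54, Mxd3 at -0.51, Mlxip at -0.47 and Mga at -0.34. Mxd4 (0.10), Mlx (-0.10) and Mlxipl (-0.09) did not pass the threshold. Of 13 tested members, Max included, 5 were higher and 5 lower, over all genes and adjusted over the list alone. As a set the list did not pass the test against other genes (camera adjusted p = 0.925); its median was -0.09, its mean 0.36 and the test pointed up. Without Max, restored by design, the mean of the other 12 was 0.03, the median -0.10 and the test pointed down (adjusted p = 0.642).

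**Figure D1:**
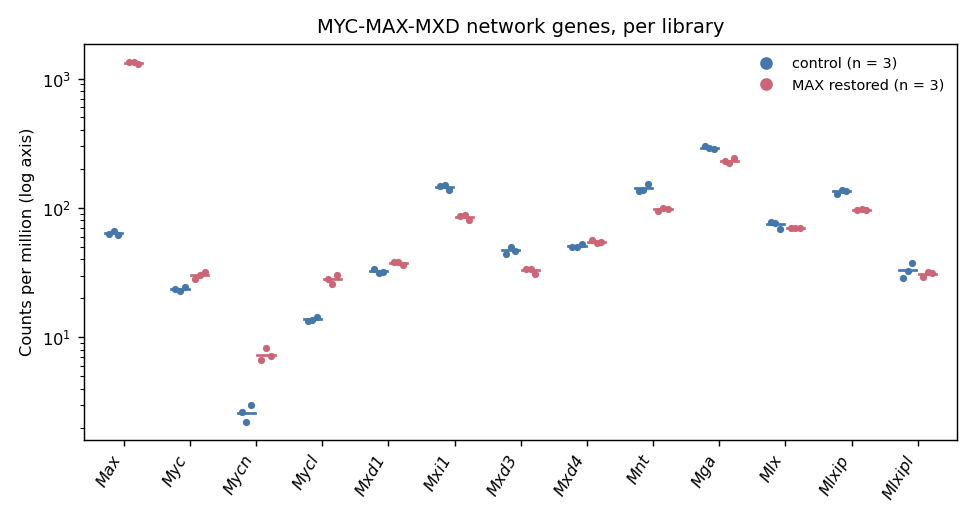
CPM of the 13 network genes in each library on a log axis, with control libraries in blue, MAX restored libraries in red and a bar at each group mean (n = 3). Max stands at 63.5 CPM in the controls and 1327 CPM in the MAX restored libraries.

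The change reached most of the transcriptome, with 3948 genes higher and 4092 lower among 12664 tested (adjusted p under 0.05). Most shifts were small: the median absolute log2 fold change of the 8040 called genes was 0.40, and 779 rose and 301 fell by at least 1. Without control 1 the counts were 4033 higher and 4219 lower. In 67.1% of tested genes the CPM values of the groups did not overlap, where chance gives 10%. The largest rises were AI593442 (log2 5.48, SE 0.23), Rtn1, a reticulon of the endoplasmic reticulum found mainly in neurons (5.40, SE 0.17), the small GTPase Rab32 (4.97, SE 0.44) and Duoxa2, a maturation factor of the dual oxidase DUOX2 (4.91, SE 0.15). They were followed by Scn2b, a sodium channel subunit, at 4.90 (SE 0.09), then the sulphotransferase gene Chst1 (4.65), the ganglioside synthase gene St8sia1 (4.59), Nsg1, a neuronal endosomal protein (4.56), Adarb2 (4.51) and the protocadherin gene Pcdha8 (4.49). Scn2b went from 2.77 ± 0.199 to 82.8 ± 2.52 CPM and Rtn1 from 0.715 ± 0.194 to 30.9 ± 2.29 CPM (SD, n = 3). Rab32 rested on 5 control counts against 183, a ratio of 33.6 (95% counting interval 14.1 to 105). All 5 lay in control 2, so that library sets the ratio.

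The deepest fall was in the keratin gene Krt19, on chromosome 11 of mm9 from 100002126 to 100007233, which went from 73.7 ± 4.38 to 0.764 ± 0.289 CPM (SD, n = 3; log2 -6.60, SE 0.13). Tenm2, a teneurin of the cell surface, fell from 213 ± 16.1 to 3.95 ± 0.843 CPM (log2 -5.74, SE 0.09) over chromosome 11 from 35820158 to 36757743. Prrg1 and Lrch2 fell almost to zero, and their fitted values of -6.24 and -5.54 depend on the prior count. Prrg1 held 166 control counts against 2, a ratio of 90.4 (95% counting interval 24.6 to 753), and Lrch2 187 against 4, a ratio of 50.9 (19.6 to 189). Other large falls were in Rgs7bp (-4.84), the interferon-induced membrane protein gene Ifitm3 (-4.16), 9130008F23Rik (-4.08), the ankyrin gene Ank2 (-3.73) and Esp8 (-3.68). In MAX restored libraries 1, 2 and 3 the counts were 1, 4 and 2 for 9130008F23Rik, 7, 1 and 1 for Ank2, and 5, 5 and 1 for Esp8. The size of these 3 falls thus depends on few reads and on single libraries. Pcdha8 shares its last exons with other genes of its cluster, and Esp8 has close relatives, so both values rest on the reads that the counting could assign.

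**Figure D2:**
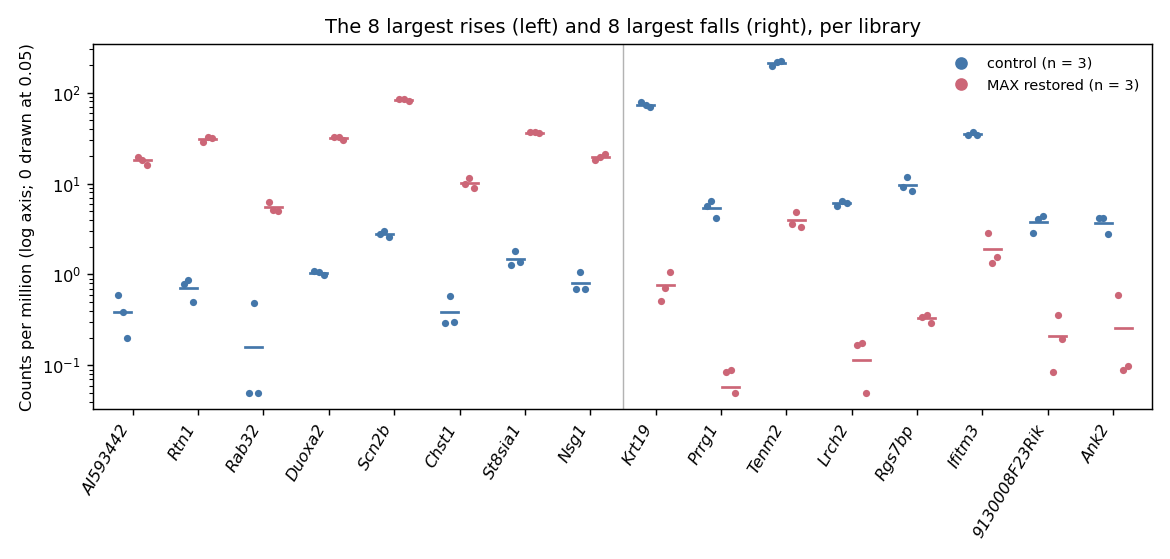
CPM per library on a log axis for the 8 largest rises and the 8 largest falls, with control libraries in blue, MAX restored libraries in red and bars at the group means (n = 3). Points with 0 counts are drawn at 0.05. That the groups do not overlap was a condition for choosing these genes.

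Genes of ribosome production fell together. All 40 tested ribosome biogenesis genes were lower, over all genes and adjusted over the list alone, with a median log2 fold change of -0.64 and a range from -1.13 to -0.27. Rcl1, an rRNA processing factor, fell 2.19-fold, Rrp12 1.84-fold, Ftsj3 1.72-fold and the nucleolar helicase Ddx21 1.68-fold. Cytosolic ribosomal protein genes were lower in 47 of 75 and higher in 1, Rpl11 (1.92 to 3.17 CPM), with 27 not past the threshold. Rpl4 fell 1.51-fold, Rps20 1.77-fold and Rpl22l1 5.22-fold. Mitochondrial ribosomal protein genes were lower in 53 of 73, with Mrpl38 down 2.14-fold and Mrpl2 1.55-fold, and higher in Mrpl20 and Mrpl49. Against other genes, camera with a preset correlation of 0.01 gave adjusted p = 2.12e-13 for ribosome biogenesis, 4.73e-07 for cytosolic and 3.18e-08 for mitochondrial ribosomal proteins. With an estimated correlation the adjusted p was 0.0336, 0.0859 and 0.0747. Ribosome biogenesis was the only 1 of 10 lists past the preset test that also passed with an estimated correlation. Its estimated correlation, 0.0096, and that of canonical MYC targets, 0.0064, lay under the preset 0.01. Their unadjusted camera p still rose, from 9.23e-15 to 0.00146 and from 5.96e-06 to 0.00934. Correlation among genes therefore does not account for the rise in these lists. Many cytosolic ribosomal protein genes have near-identical pseudogenes, so their counts are uncertain. Rpl11 and Mrpl20 lie in the chromosome 4 stretch described with the genomic positions.

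Genes of serine use, of the ATF4 amino acid response and of purine synthesis were mostly lower. In the serine and one-carbon list 21 of 27 tested genes fell, Shmt1 by 2.69-fold from 165 ± 0.717 to 61.2 ± 0.0830 CPM (SD, n = 3). Shmt2, the mitochondrial serine hydroxymethyltransferase, fell 2.03-fold, the serine synthesis gene Psat1 1.99-fold and Mthfd2 1.90-fold. Of 3 that rose, Aldh1l1 (log2 3.03) and Tyms (0.13) were chosen after their values were seen. The list was written in the knowledge that the laboratory has published on this pathway, so its direction is not independent evidence. Of 28 ATF4 targets 26 fell, among them Atf4 itself (1.89-fold), the asparagine synthetase gene Asns (2.07-fold), Trib3 (2.51-fold) and Eif4ebp1 (2.61-fold). Gdf15 rose (log2 0.81). Purine synthesis genes were lower in 13 of 17, including Atic (1.70-fold) and Pfas (1.47-fold), while Adssl1 (0.54) and Prpsap2 (0.43) rose. Prps1 (-0.55) and Prps2 (-0.60) also fell, and both lie in the chromosome X stretch, where 59 of 89 genes were lower. Gdf15 lies in a chromosome 8 stretch. Camera adjusted p was 3.43e-05, 6.43e-10 and 0.00326 for the serine, ATF4 and purine lists. With an estimated correlation it was 0.0859, 0.0859 and 0.136.

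Canonical MYC targets fell in 21 of 25, although Mycn, Mycl and Myc rose. The hexokinase gene Hk2 fell 3.77-fold, from 187 ± 17.2 to 49.6 ± 2.44 CPM (SD, n = 3), Nme2 2.15-fold and Ldha 1.54-fold. The transferrin receptor gene Tfrc rose 2.15-fold and Tert rose by log2 0.84. Camera adjusted p was 2.29e-05, and adjusted p = 0.0747 with an estimated correlation. Nme1 and Nme2 are neighbours of similar sequence, so reads that match both could be missing from their counts. Glycolysis genes, which share Hk2 and Ldha with that list, moved both ways, 5 higher and 10 lower of 21, and as a set did not pass the test against other genes (adjusted p = 0.338). Adjusted over the list alone, 6 were higher. Of 29 tested targets of the hypoxia factor HIF, a list chosen after the data were seen, 12 are also glycolysis list members. In control 1, 24 of the 29 lay above the mean of the other controls (median log2 0.14). With MAX restored 19 of the 29 were lower and 4, Tpi1, Higd1a, Kdm3a and Gbe1, higher (median log2 -0.32). Pfkp fell 1.75-fold and the lactate transporter gene Slc16a1 1.95-fold, while Pfkm, Hk1, Eno2, Aldoc and Tpi1 were the 5 that rose. Complex I subunit genes were lower in 22 of 35, among them Ndufa6 (log2 -0.52) and Ndufb9 (-0.38), and higher in Ndufb10, Ndufb7 and Ndufb3. The adjusted p of 0.00326 for complex I became 0.347 with an estimated correlation and 0.812 with the gene length trend removed.

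Replication and mitosis genes were lower in 30 of 35 and higher in none. Rrm2, a ribonucleotide reductase subunit, fell 2.02-fold, from 362 ± 16.2 to 179 ± 7.71 CPM (SD, n = 3). The mitotic genes Top2a, Kif11 and Aurkb fell 1.56-fold, 1.62-fold and 1.65-fold. E2f2, Pcna, Mcm5, Ccne2 and Mcm2 did not pass the threshold. Camera adjusted p was 3.13e-07 and, with an estimated correlation, adjusted p = 0.199. Growth arrest and apoptosis genes went both ways, with 11 higher and 8 lower of 23 (adjusted p = 0.504). The cyclin-dependent kinase inhibitor gene Cdkn1c rose from 21.4 ± 0.476 to 66.3 ± 1.90 CPM (SD, n = 3), Gadd45b 1.76-fold, Klf6 1.57-fold and Ccng2 1.55-fold. Adjusted over that list alone, 9 were lower. Of 73 histone genes only 14 had enough counts to be tested, so most of the family is not covered. Of the 14, 9 were higher, and H2afx and H3f3b were lower. Hist1h2bc rose 5.31-fold, Hist1h1c 2.81-fold and Hist3h2a 2.06-fold, though many histone genes are near-identical copies and their counts are uncertain. The histone adjusted p was 0.0345, and 0.407 with an estimated correlation; it was 0.0528 without control 2 and 0.0618 without control 3.

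**Figure D3:**
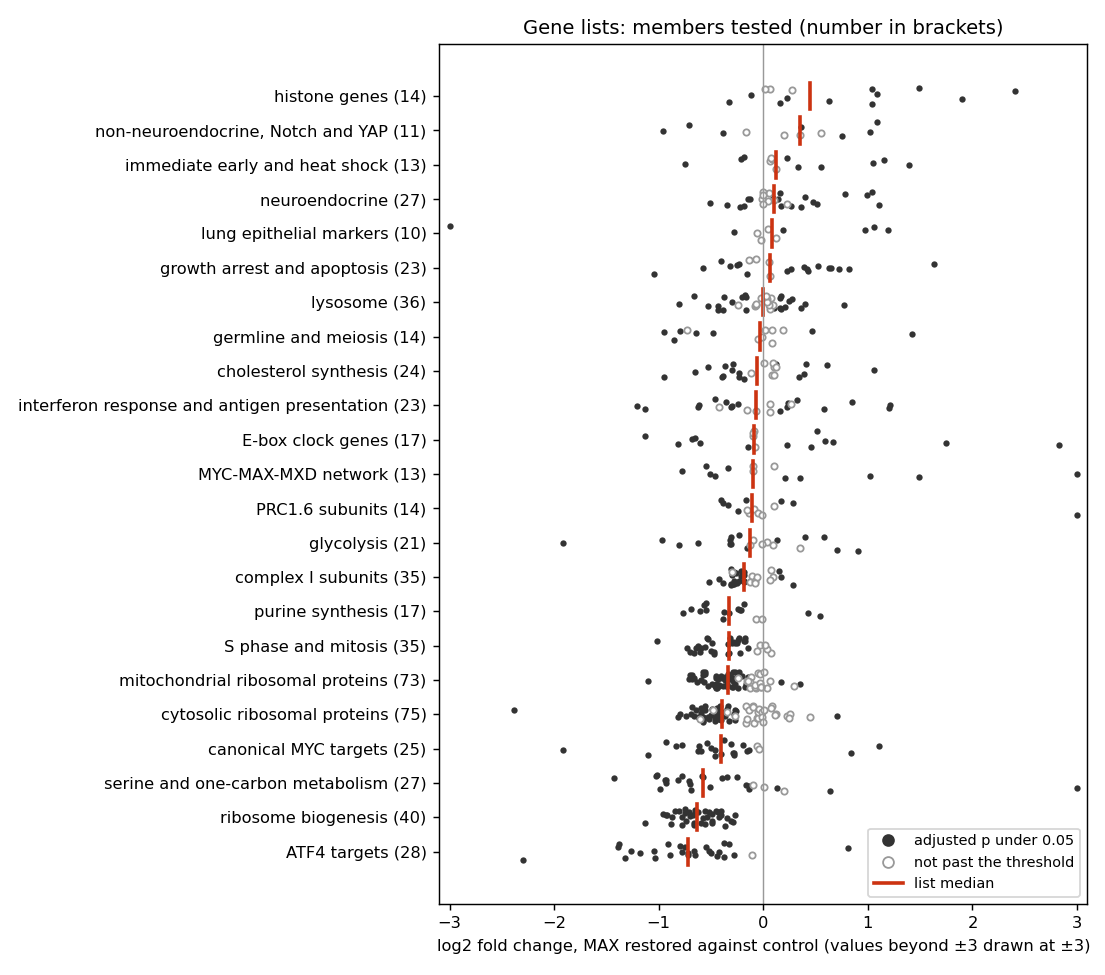
Log2 fold change, MAX restored against control, of each tested member of the 23 lists with at least 3 tested members, with filled points past adjusted p 0.05, open points not past it and a red bar at each list median. Values beyond 3 are drawn at 3; the ribosome biogenesis members all lie below 0, with a median of -0.64.

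Neuroendocrine genes, which mark the cell type of small cell lung cancer, were higher in 13 of 27 and lower in 6. The granule genes Scg2, Chgb and Pcsk2 rose 2.05-fold, 1.99-fold and 2.15-fold, and the splicing factor gene Celf3 1.72-fold, while Foxa2, Scg3, Nkx2-1, Nfib and Srrm4 were among those that fell. Against other genes the list gave adjusted p = 0.0902, and 0.219 with an estimated correlation. Of 24 genes of the non-neuroendocrine, Notch and YAP programme only 11 had enough counts to be tested, so most of the list is not covered. Vim, Rest and Axl were among those not tested. The 11 split 4 higher to 3 lower (camera adjusted p = 0.645). Hey1, a Notch target, rose 2.13-fold, Notch2 2.03-fold and Zeb1 1.69-fold, with Cd44 also higher; Hes1, another Notch target, fell 1.95-fold, with Yap1 and Anxa1 also lower. Among the 10 of 18 lung epithelial markers tested 4 rose and 2 fell (camera adjusted p = 0.604, median 0.08, mean -0.34, test up). Krt8 rose 2.08-fold, Foxj1 2.29-fold and Krt18 1.14-fold, with Ager also higher; Krt19 and Sftpc fell. Few markers of other cell types had enough counts to be tested. The fibroblast markers Pdgfrb (0.525 to 1.86 CPM) and Tagln (2.58 to 4.01 CPM) were the 2 of 12 tested, and both rose. The immune markers Lyz2 (0.810 to 1.14 CPM, log2 0.48) and Cd68 (1.43 to 1.58 CPM, 0.12) were the 2 of 11 tested and did not pass. Of 8 endothelial markers only Vwf was tested, and it was abundant. It fell 1.29-fold, from 559 ± 28.2 to 432 ± 17.8 CPM (SD, n = 3).

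PRC1.6 is a polycomb complex that contains MAX and MGA and silences germline genes. Of its 14 subunit genes 3 were higher, namely Max, Rybp and Tfdp1, and 5 lower. The 5 were Wdr5 (log2 -0.41), L3mbtl2 (-0.38), Mga (-0.34), Pcgf6 (-0.24) and Yaf2 (-0.17). The median was -0.11, the mean 0.21 and the test down (adjusted p = 0.604). Without Max, restored by design, the mean of the other 13 was -0.11, the median -0.13 and the test down (adjusted p = 0.261). Of 48 germline and meiosis genes only 14 had enough counts to be tested. Syce2 fell 1.93-fold, Tex15 1.56-fold, Stag3 1.39-fold and Cpeb1 1.74-fold, and Msh5 was the fifth to fall; Tdrd9 and Piwil4 rose. As a set the list did not pass the test against other genes (adjusted p = 0.254). Both lists were written knowing the laboratory's earlier work, so their direction is not independent evidence. Syce2 lies in a chromosome 8 stretch where 48 of 60 genes were higher.

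Of the remaining lists none passed the test against other genes as a set, though single members moved far. Clock rose 3.36-fold, from 225 ± 6.45 to 758 ± 35.8 CPM (SD, n = 3), while Cry1 fell 2.20-fold, Per1 1.76-fold and Usp2 1.52-fold. In that list of E-box clock genes 7 of 17 were higher and 6 lower (adjusted p = 0.716; median -0.09, mean 0.15, test down); adjusted over the list alone, 7 were lower. Interferon and antigen presentation genes split 8 to 9 of 23 (adjusted p = 0.765), with Stat2 up 1.81-fold, Tap1 down 1.54-fold, H2-K1 down 1.28-fold and Bst2 down 2.31-fold. Immediate early and heat shock genes were higher in 6 and lower in 3, Nr4a1, Hsph1 and Junb, of 13 (adjusted p = 0.236). Egr1 rose 2.62-fold, Fos 2.23-fold and Dusp1 1.46-fold. Cholesterol synthesis genes split 6 to 11 of 24 (adjusted p = 0.645), with Hsd17b7 down 1.94-fold, Mvd down 1.57-fold and Stard4 down 1.45-fold. Adjusted over that list alone, 7 rose and 12 fell. Lysosomal genes split 11 to 13 of 36 (adjusted p = 0.654), with Psap up 1.32-fold, Gaa down 1.44-fold, Hexa down 1.35-fold and Ctsz down 1.31-fold. Unless a second count is given, adjusting over a list alone gave the same counts as adjusting over all genes.

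In some stretches of the genome neighbouring genes shifted together. The last stretch of chromosome X, from 136902033 to 166428729 in mm9, was lower, with a median log2 fold change of -0.55 over 89 genes and 59 of them called lower. Outside the stretch X had a median of 0.01 over 320 genes. The end of chromosome 4, from 135411986 to 155198652, was higher, with 148 of 193 genes called higher and a median of 0.44, against -0.01 over the 624 other genes of the chromosome. On chromosome 8 a stretch from 59961499 to 86520341 (172 genes, median 0.38) and another from 87380885 to 96536540 (60 genes, median 0.41) were higher. The 477 genes of chromosome 8 outside both had a median of 0.06, with 182 higher and 126 lower. These stretches hold windows of 51 neighbouring genes whose median passed 0.388, the most extreme value in 1000 shuffles of the fold changes over gene positions. Their limits are the outermost genes of such windows, so genes near an edge may lie outside the shift. A stretch of chromosome 18, from 35830759 to 39078353, also passed, and 44 of its 79 genes were protocadherins. Its median was 0.25, and 0.11 without them. Among the genes chosen by rule, Lrch2, Prps1 and Prps2 lie in the X stretch, Bst2 and Syce2 in those on 8, and Pcdha8 in that on 18. Of these, Prps1 and Syce2 lie close to an edge.

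**Figure D4:**
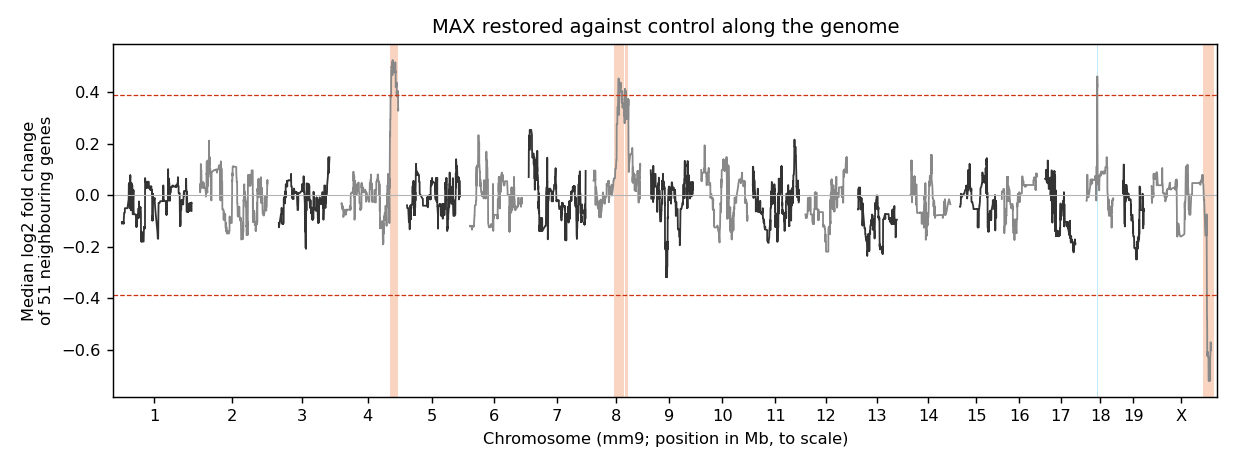
Median log2 fold change, MAX restored against control, of 51 neighbouring tested genes along chromosomes 1 to 19 and X (mm9, positions in Mb to scale). Dashed lines mark 0.388 on each side of 0, orange shading marks the 4 stretches on X, 4 and 8, and blue shading the protocadherin stretch on 18.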

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

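The alternatives without Max in the lists, without rRNA-like genes, without the genes of the shifted stretches and with the GC trend removed were chosen after the data had been seen; all others were planned. Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.0035, 0.035 and -0.024, and not every library correlated best with its own number. The fit with the replicate number as a block gave 3941 genes higher and 4093 lower, against 3948 and 4092. Leaving out 1 library gave between 3618 and 4033 genes higher and between 3640 and 4219 lower. DESeq2 gave 3318 and 3534 of 15089. Of the 8040 main calls DESeq2 kept 6697, the fit with the length trend removed 7251, and the fit without MAX restored 1 7124. Kept calls had the same direction in every alternative run. The alternatives reuse these same libraries, so this is no independent check. A log2 fold change of at least 1 left 779 and 301; this setting and DESeq2 gave no list test. With an estimated correlation the adjusted p was 0.0859 for the serine and one-carbon, ATF4 and cytosolic ribosomal protein lists, 0.0747 for MYC targets and mitochondrial ribosomal proteins, 0.136 for purine synthesis, 0.199 for S phase and mitosis, 0.347 for complex I and 0.407 for histones. Fry, which asks another question, gave 1.85e-05 for the neuroendocrine list, 0.00319 for germline genes and growth arrest, 0.0044 for glycolysis, 0.0027 for cholesterol synthesis, 0.00643 for immediate early genes, 0.019 for lung epithelial markers. The network (1.85e-05, up) and PRC1.6 (3.86e-05, up, opposite to camera) lists hold Max, restored by design, which largely set these values; without it fry gave 0.00556 and 0.000367, both down, and camera 0.642 (down) and 0.261. The histone p of 0.0345 misses a threshold of 0.01, was 0.119 without a filter on low counts, and ranged from 0.0165 to 0.0618 with 1 library left out (0.00412 to 0.119 over the camera alternatives with a preset correlation). Complex I gave 0.812 with the length trend removed and 0.731 with the block as well (range 0.000346 to 0.812). Neuroendocrine genes passed with limma voom, 0.0347 (range 0.0347 to 0.146). With camera, signs turned, always without a call, for the network list with no filter (0.944), voom (0.894) and the GC trend removed (0.924), and without control 1 (0.973), though not without any other library (0.876 to 0.973 over all 6); for lung epithelial markers with no filter (0.926); and for interferon genes without the shifted stretches (0.994). Among genes not called with all libraries, leaving 1 out gave Mlxipl a log2 fold change from -0.18 (past the threshold, without control 1) to 0.0022, Lyz2 from -0.035 to 0.93 and Cd68 from -0.14 to 0.30. In all of these the cause was not tested. The smallest simulated changes were recovered in 55.1% of cases. The simulation changed far fewer genes than the 8040 of 12664 called here, so that rate does not carry over directly. Small changes can still be missed.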

Other observations

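The groups of genes sharing the first letters of a symbol, the tests on chance placement, GC content and length of the stretches, copy number, ribosomal RNA reads, hypoxia targets, and the length, GC and cycling tests on ribosome genes were chosen only after the result was seen. Of 120 such symbol groups 16 passed camera with a preset correlation, and 0 passed with an estimated correlation. As the ribosome biogenesis list showed, such a rise in p need not come from correlation among genes. Of the 16, 12 were lower (Mrp, Rps, Eif, Pol, Rpl, Nup, Ndu, Psm, Tim, Cen, Rad and Snr) and 4 higher (Pcd, Gpr, Cas and Kcn). Log2 fold change rose with exon length (Spearman 0.173), and the groups were not retested with that trend removed. Mrp, Rps, Rpl and Ndu share members with the fixed lists. Of these lists, complex I gave a camera adjusted p of 0.812 with the length trend removed. Protocadherin and related genes (Pcd) were higher in 32 of 48 and lower in 4 (adjusted p = 0.000225); all but 4 of the 48 lie in the shifted stretches. Genes with Gpr symbols, the stem of G protein-coupled receptor genes, were higher in 23 of 38 and lower in 5 (adjusted p = 0.0133). Those with Kcn symbols, the stem of potassium channel genes, were higher in 30 of 52 and lower in 11 (adjusted p = 0.0438). Genes with Eif symbols, which take in Eif4ebp1 beside translation initiation factors, were lower in 36 of 52 and higher in 2 (adjusted p = 0.000307). Those with Nup symbols, the stem of nuclear pore genes, were lower in 17 of 24 and higher in 1 (adjusted p = 0.00612). The lowest adjusted p of any of these groups was 0.311 with an estimated correlation.

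Of the 10 splits of the 6 libraries into 3 and 3, the real 1 called 8040 genes and the highest other 0. Every other split mixes the groups, so the difference between them becomes spread within each side and few calls were bound to follow. With 10 splits a share under 0.05 is also out of reach, so the splits decide nothing.

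Neighbouring genes of 4 stretches on chromosomes X, 4 and 8 moved together. Of 1000 further shuffles of the fold changes over gene positions 0 reached the weakest of the 4, but the stretches had been picked for passing the most extreme of earlier shuffles, so this count adds nothing. The earlier 1000 shuffles themselves argue against chance placement of single genes. Their largest window medians anywhere had a 95th percentile of 0.293 and a maximum of 0.388. Windows in the stretches reached -0.72 on X, 0.52 on 4, and 0.45 and 0.41 on 8. With GC content and length regressed out the stretches kept at least 71.9% of their medians (lower bootstrap bounds from 60.02% to 86.1%), which argues against these as the whole cause. In 10 of 12 expression classes the share of genes on the stretch's side lay inside the 95% range of a common shift. Both misses lay below it. They were the highest class on X (83.3% against 86.7% to 100%) and the middle class of the first chromosome 8 stretch (66.7% against 73.7% to 93.0%). On X the share lay below the mean prediction in every class, and the interquartile range was 0.80 against 0.53 for all genes. Each stretch reached to the outermost genes of its passing windows. Unshifted genes at an edge could therefore also lower a share and widen the range. The stretch's own median set each shift, and coordinated regulation would give the same. A DNA copy number difference between the cell populations is therefore neither favoured nor excluded. Copy number and regulation of these neighbourhoods by MAX both stay open, as no DNA measurement was used here.

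Control 1 differed more from controls 2 and 3 than these did from each other. Without 6 rRNA-like genes the lower chi-square per degree of freedom was still 3.48, and with GC content and length trends removed as well 2.60, which argues against either as the whole cause. A hypoxia-type response may contribute: the median of 29 HIF targets lay at percentile 100 of 10000 matched lists, and also without the 4 targets already seen to differ. The matched lists drew genes singly, so any set of genes varying together in this library could reach that percentile. Of the 29, 12 are glycolysis list members, but the shift was not confined to them. Outside that list Ankrd37 (log2 0.39), Bnip3l (0.32) and P4ha2 (0.30) were also higher in control 1. Whether the shift is particular to hypoxia was not tested. Slc2a1 (log2 -0.03), Vegfa (-0.05), Ddit4 (-0.01), Gpi1 (-0.04) and Gys1 (-0.10), all HIF targets, were not higher in control 1. The design names no biological difference between controls, and no other biological explanation was tested.

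All 40 ribosome biogenesis genes were lower with MAX restored. With the length trend removed 40 stayed lower, and with the GC trend removed 40, which argues against both trends as the cause. A lower share of cycling cells as the whole cause is argued against by medians: the ribosome list lay below the S phase and mitosis list by a log2 difference of -0.31 (permutation p = 2e-05 across genes, which are not independent). That MAX itself lowers these genes is a hypothesis and may be so, but an effect of doxycycline or of the vector stays open. The labels do not say whether the control arm had either. Another difference between the cell populations, such as the copy number difference left open for the shifted stretches, was not tested as a cause.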
